A study of Homo sapiens with 6 samples.

How the data were processed

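RNA was taken from THP-1 cells treated with PMA at 100 ng/mL for 24 h and interleukin-4 at 20 ng/mL for 48 h, transfected with 4 ug of plasmid for 6 h and cultured for a further 48 h, per the labels. The plasmid was pcDNA3.1, empty in 3 libraries and carrying WTAP in the other 3. Polyadenylated RNA was sequenced in pairs of 150 bp reads.

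The authors deposited estimated counts per gene, which need not be whole and are not scaled between libraries, and TPM per gene, per the file headers. The submitters' processing notes name fastp 0.19.5, HISAT2 2.1.0, StringTie 2.1.2 and RSEM 1.3.3, with no role or order, and the GRCh38 build. Whether counting used strand is not given in the sources used here, so genes that overlap on opposite strands are treated as uncertain. Each table held 63241 genes, of which 20601 had no gene name, and 2 columns of the authors' group means that were not used. In each library between 5908 and 6686 genes had a count that was not whole. Counts that are not whole are the kind RSEM gives, which splits reads that fit several transcripts by likelihood, so close copies may share counts. TPM divides each library by its own sum over length-scaled counts, so a library with more reads on short genes has lower TPM for long ones.

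Estimated counts were rounded to whole numbers. Depth was 19232036 to 22411157 estimated counts per library. In the fit chosen before the data were examined, genes passed edgeR's filterByExpr (14926 genes), libraries were scaled by TMM (factors 0.975 to 1.042), and groups were compared with the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 16%. CPM values are TMM-normalized. The SE of a log2 fold change is its size over the square root of F, and 95% intervals use the test's degrees of freedom. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. DESeq2 ran with default settings on genes with a count above 0 and gave an adjusted p to 15071 genes.

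A total of 39 gene lists were fixed before the data were examined, and 37 had the 3 tested members required. They cover the m6A machinery, macrophage polarisation, interferon, NF-kB, inflammasome, lipid, energy, stress, cell cycle, splicing, lysosome, antigen presentation, matrix and TGF-beta genes, markers of other cell types, and signs of RNA quality. Lists were compared with all other genes by limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 37 lists. No call held with an estimated correlation, a setting that also leaves only the residual degrees of freedom of the 6 libraries. A call lost there need not reflect correlated members where the estimate lay near 0.01, as for ATF4 targets (0.026) and matrix genes (0.043). The estimate was far higher for ribosomal proteins (0.931), mitochondrially encoded genes (0.775) and oxidative phosphorylation (0.595). It was 0.389 for endoplasmic reticulum chaperones, 0.33 for G2 and mitosis and 0.25 for cholesterol synthesis. The preset understates the correlation of these lists, so their camera p may be too small. The text names WTAP, its writer partners, the 10 steepest rises and falls among called genes whose groups do not overlap and whose higher group has a mean of at least 1 CPM, up to 4 called members of each list or else the 2 with the smallest p, and the 5 genes of smallest adjusted p then left. As no gene passed edgeR, the steepest rises and falls were taken from DESeq2, a choice made after seeing the data. ASNS, TRIB3, CHAC1, SESN2, SLC7A5, ATF4, DDIT3, HSPA5, HSP90B1, MMP1, MRC1, CCL22, CD163, IL1B, SOD2, TXNRD1, SRXN1, OSGIN1, MT1E and MT1F were named outside that rule, after their values were seen, as were the genes of the closing observations.

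The pairs of libraries all differed by more than sampling noise (chi-square per degree of freedom of at least 4.3), so none was a resequenced copy of another. Each was counted as a separate replicate, as labelled. The labels do not say whether the libraries are separate cultures or days, and this value cannot show it. Correlations of log2 CPM ran from 0.976 to 0.991 within groups and from 0.964 to 0.989 between them. The steps were tested on simulated counts for these 14926 genes in which 200 were changed. In this comparison edgeR recovered 93.9% of genes changed 4-fold, 73.1% at 2-fold and 23.9% at 1.5-fold, with 13 unchanged genes among 140 calls; DESeq2 recovered 92.4%, 74.6% and 31.3%, with 27 unchanged among 159. In a simulation over 37 lists and 14719 genes with only the ATF4 list raised 1.3-fold, camera called that list and 1 other. Both simulations drew genes independently and made no library stand apart. Members of the real lists correlate (estimate 0.931 for ribosomal proteins), so the simulation does not show how often camera falsely calls such lists.

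Alternatives were other scaling factors, DESeq2, limma-voom with sample quality weights, no filter and a stricter filter on low counts, the replicate number as a block, limma-trend on log2(TPM + 1) or log2(TPM + 0.1) for genes with a TPM of at least 1 in 3 libraries or above 0 in any, and leaving out each library. Lists were also tested with fry. Chosen after seeing the data were fits without the 2 libraries farthest apart on the first principal component, DESeq2 without each library, and list tests after each library's loess trend (span 0.4) on gene length or transcript GC content was removed. Coordinates, overlaps and GC content come from GENCODE release 29 on GRCh38, which held 96.3% of the genes tested.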

Results

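Polyadenylated RNA was sequenced from THP-1 cells, an established human monocytic leukaemia line. The cells were turned into macrophages with the phorbol ester PMA and polarised towards the M2 state with interleukin-4, the cytokine of alternative macrophage activation. They were then transfected with an empty pcDNA3.1 plasmid or with the same plasmid carrying WTAP. WTAP is a regulatory subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Each group held 3 libraries that the labels call biological replicates. Total estimated counts were 22411157, 21709079 and 19486170 in empty vector replicates 1, 2 and 3, and 19828402, 19934067 and 19232036 in the libraries labelled WTAP overexpression. The question was which transcripts differ in M2-polarised macrophages given WTAP.

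WTAP itself was about as abundant in both groups. It reached 93.3 ± 10.1 CPM with empty vector and 102 ± 6.16 CPM in the libraries labelled WTAP overexpression (SD, n = 3 each). The fold change was 1.1, with a 95% interval from 0.913 to 1.32. On the log2 scale this was 0.13 ± 0.12 (SE), with an edgeR adjusted p of 0.675, and an exact two-sided permutation test on log2 CPM gave p = 0.3, where 3 against 3 cannot go below 0.1. Counts ran from 1623 to 2285 per library, so a 2-fold rise lay outside the interval. In the deposited TPM values, WTAP was 84.7 ± 2.79 with empty vector and 102 ± 6.8 in the other group (SD, n = 3 each), and the groups did not overlap. The same permutation test on log2(TPM + 1) gave p = 0.1, the lowest it can give. The median gene also lay 0.13 higher (log2) on the TPM scale than on the CPM scale, and WTAP, at 0.27, stood 0.13 above that shift. WTAP (ENSG00000146457) lies on chromosome 6 from 159725585 to 159756319 on GRCh38, on the plus strand, and shares exonic positions with SOD2 on the opposite strand. SOD2, a mitochondrial superoxide dismutase, had 5.11 times the counts of WTAP, so part of either value is uncertain where the counting did not use strand. Because the labelled gene did not stand out, directions below are those of the libraries labelled WTAP overexpression.

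**Figure D1:**
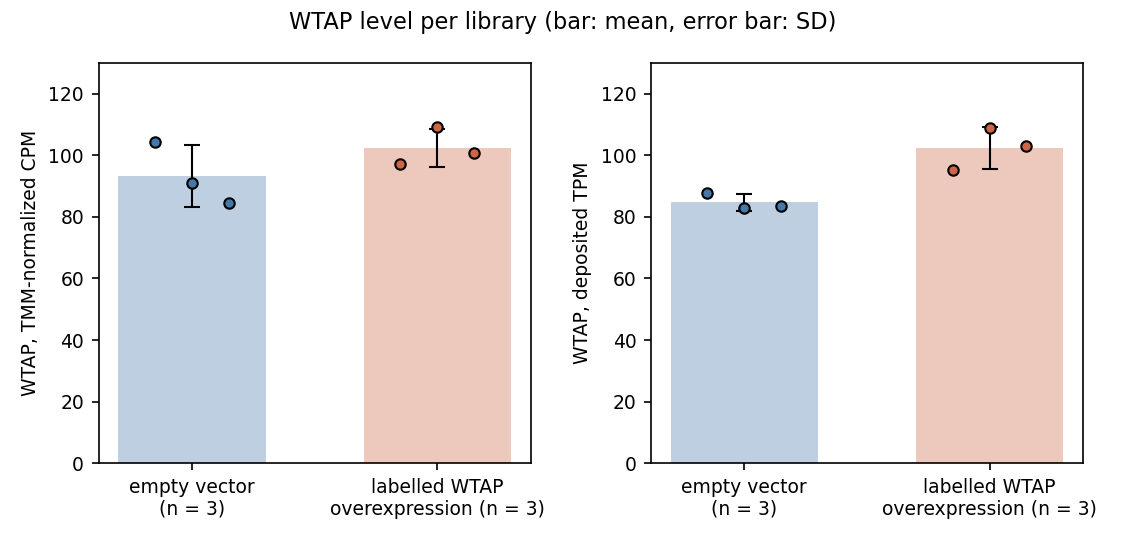
WTAP level per library as TMM-normalized CPM (left) and as the deposited TPM (right); points are libraries, bars are means and error bars are SD of 3 libraries. CPM values overlap between groups (84.6 to 104 with empty vector, 97.3 to 109 with the WTAP label), while TPM values do not.

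No partner of WTAP in the writer complex passed the test. Of the 7 measured, 6 lay higher and METTL3, the catalytic methyltransferase, lay lower, at 20.9 ± 1.26 against 26.2 ± 1.04 CPM (SD, n = 3 each; log2 fold change -0.33 ± 0.12 SE, edgeR adjusted p = 0.346). METTL3 overlaps TOX4, which has 295% of its counts, so its value is uncertain. METTL14, the partner methyltransferase, differed by 0.19 ± 0.15, and VIRMA, the scaffold subunit, by 0.07 ± 0.12. CBLL1 lay at 0.21, RBM15 at 0.22, RBM15B at 0.15 and ZC3H13 at 0.14. METTL14 lay at -0.01 on the TPM scale, RBM15B turned to -0.03 without the 2 libraries farthest apart, and RBM15B overlaps DCAF1. Without 1 library METTL14 ran from 0.092 to 0.346 and RBM15B from 0.04 to 0.214. None of the 7 passed a test over all genes or when adjusted over the list alone. The list had a camera adjusted p of 0.34, and 0.0408 with fry, which does not compare it with other genes. The list of erasers and readers, led by HNRNPA2B1 (-0.21) and FMR1 (0.18), had 0.661, with 9 of 13 members higher.

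**Figure D2:**
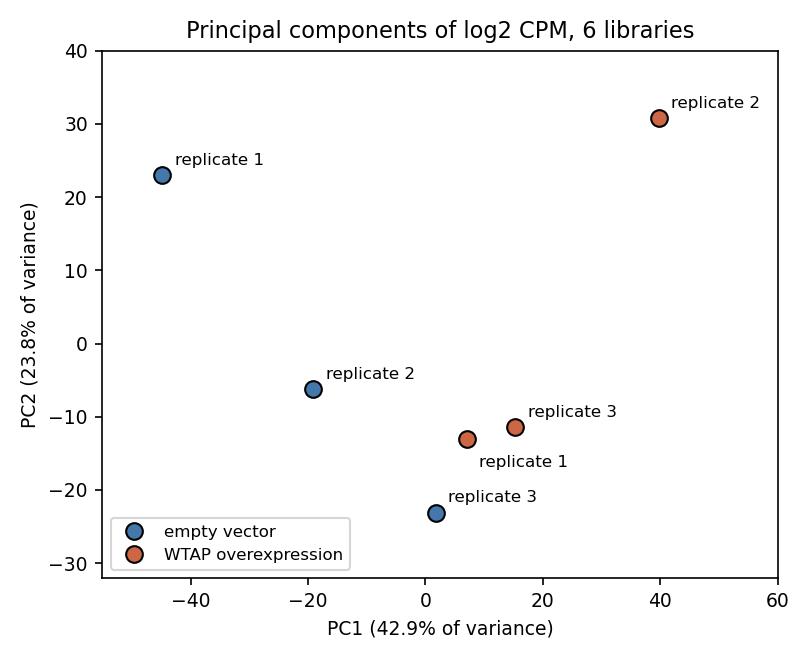
The first and second principal components of log2 CPM over 14926 genes, holding 42.9% and 23.8% of the variance; each point is a library. The first axis runs from empty vector replicate 1 at -44.8 to WTAP-labelled replicate 2 at 39.7, and empty vector replicate 3 (1.8) lies nearest to WTAP-labelled replicate 1 (7.0).

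The single genes with the smallest p were FCRLB, COL5A3 and FCRLA, all lower in the libraries labelled WTAP overexpression. FCRLB fell from 31.2 ± 1.67 to 14.7 ± 0.44 CPM (SD, n = 3 each; log2 fold change -1.09 ± 0.12 SE, DESeq2 adjusted p = 4.69e-09), and its neighbour FCRLA fell from 310.4 ± 39.7 to 132 ± 25.9 CPM (-1.23 ± 0.16, DESeq2 adjusted p = 4.69e-09). COL5A3, a fibrillar collagen chain, had a log2 fold change of -1.36 ± 0.18, SLA, an adaptor of receptor signalling, of -1.02 ± 0.15, and BPI, an antibacterial granule protein, of -1.05 ± 0.17; DESeq2 called each of these lower. These calls hold for DESeq2 and not for the test fixed in advance. With edgeR's quasi-likelihood test no gene passed among 14926 (0 called; smallest adjusted p 0.0714, FCRLB), although 1813 had an unadjusted p under 0.05 where 746 would come by chance. DESeq2 called 198 genes, 66 higher and 132 lower, of which 78 differed at least 2-fold. Limma-voom with sample quality weights called 2296. It weighted the libraries very unequally, from 0.227 for empty vector replicate 1 and 0.344 for WTAP-labelled replicate 2 to 4.57 for empty vector replicate 2. The groups did not overlap in 2787 genes (18.7%, where chance gives 10%). The DESeq2 count was 24 without empty vector replicate 2, 55 without WTAP-labelled replicate 3, 74 without WTAP-labelled replicate 2 and 626 without empty vector replicate 3. In the paragraphs below, "called" for a single gene means by DESeq2.

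Among genes that DESeq2 called and whose groups did not overlap, the steepest falls were in SUN3 (log2 fold change -3.21 ± 0.70 SE), the chemokine CCL1 (-2.36 ± 0.51), NPTX2 (-2.14 ± 0.38), PLPPR4 (-2.08 ± 0.40), NXPH3 (-2.06 ± 0.45), the macrophage elastase MMP12 (-1.99 ± 0.44), the metallothionein MT1G (-1.96 ± 0.45), DUSP13B (-1.92 ± 0.37), SERPINA9 (-1.90 ± 0.37) and the apolipoprotein APOA1 (-1.81 ± 0.49). Of these, MMP12 was the most abundant, at 964 ± 342 CPM with empty vector and 243 ± 139 CPM with the WTAP label. The steepest rises were in the cytokine receptor IL31RA (2.15 ± 0.41), AKR1C1 (1.56 ± 0.38), CSF2RA (1.42 ± 0.35), TRIM16L (1.41 ± 0.33), NMRAL2P (1.3 ± 0.30), the inhibitory receptor LAIR1 (1.24 ± 0.36), the endothelin receptor EDNRB (1.15 ± 0.20), the histone gene H4C15 (1.11 ± 0.23), the death ligand TNFSF10 (1.11 ± 0.25) and SULT1C2 (1.10 ± 0.21). Without WTAP-labelled replicate 2, LAIR1 lay at 0.62 and CSF2RA at 0.95, and SUN3 lay at -5.38 without WTAP-labelled replicate 1. Most of the risen genes were scarce; IL31RA went from 0.306 ± 0.019 to 1.37 ± 0.527 CPM. AKR1C1, TRIM16L, NMRAL2P, H4C15 and CSF2RA have close copies or a second entry in the annotation, so their counts are uncertain. An unnamed transcript, ENSG00000269307, was among the 5 genes with the smallest p left to name (0.778 ± 0.151 against 0.0161 ± 0.0278 CPM), but it overlaps the far more abundant BABAM1.

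Transcripts of the integrated stress response, the programme run by the transcription factor ATF4, rose as a group. Of 25 members, 18 lay higher, 13 passed as higher when adjusted over the list alone and 0 as lower, 0 passed edgeR over all genes, and DESeq2 called 7. The list's median log2 fold change was 0.37 (camera adjusted p = 6.19e-06; adjusted p = 0.457 with an estimated correlation). PSAT1, an enzyme of serine synthesis, rose from 45.5 ± 5.43 to 78.4 ± 11.1 CPM (SD, n = 3 each; log2 fold change 0.79 ± 0.14 SE). PHGDH, the first enzyme of that pathway, rose by 0.78 ± 0.14 and the asparagine synthetase ASNS by 0.72 ± 0.15. TRIB3, CHAC1, SESN2 and the amino acid transporter SLC7A5 were called too, while ATF4 (0.44 ± 0.12) passed only when adjusted over the list alone. DDIT3, which encodes the stress factor CHOP, was near 0 (0.11). The mean of the list was above its 6-library mean in all 3 WTAP-labelled libraries (0.10, 0.26 and 0.18) and below it in all 3 with empty vector (-0.20, -0.20 and -0.14). The endoplasmic reticulum chaperone, matrix and G2 lists below also separated all libraries by group, with empty vector higher.

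Endoplasmic reticulum chaperones and other unfolded protein response genes went the other way. All 20 members lay lower (19 with library size alone and 18 on the TPM scale), with a median of -0.29 (camera adjusted p = 2.04e-06; adjusted p = 0.676 with an estimated correlation). CRELD2, at 20.7 ± 1.36 against 28.4 ± 1.47 CPM (SD, n = 3 each), and the secreted chaperone MANF, at 44.7 ± 4.29 against 71.3 ± 20.0 CPM, passed when adjusted over the list alone, and DESeq2 called none. The major chaperones HSPA5 and HSP90B1 had log2 fold changes of -0.22 ± 0.13 and -0.30 ± 0.15, the latter -0.18 without WTAP-labelled replicate 2. The list's median was -0.14 without the 2 libraries farthest apart. CRELD2 overlaps ALG12, so its value is uncertain.

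**Figure D3:**
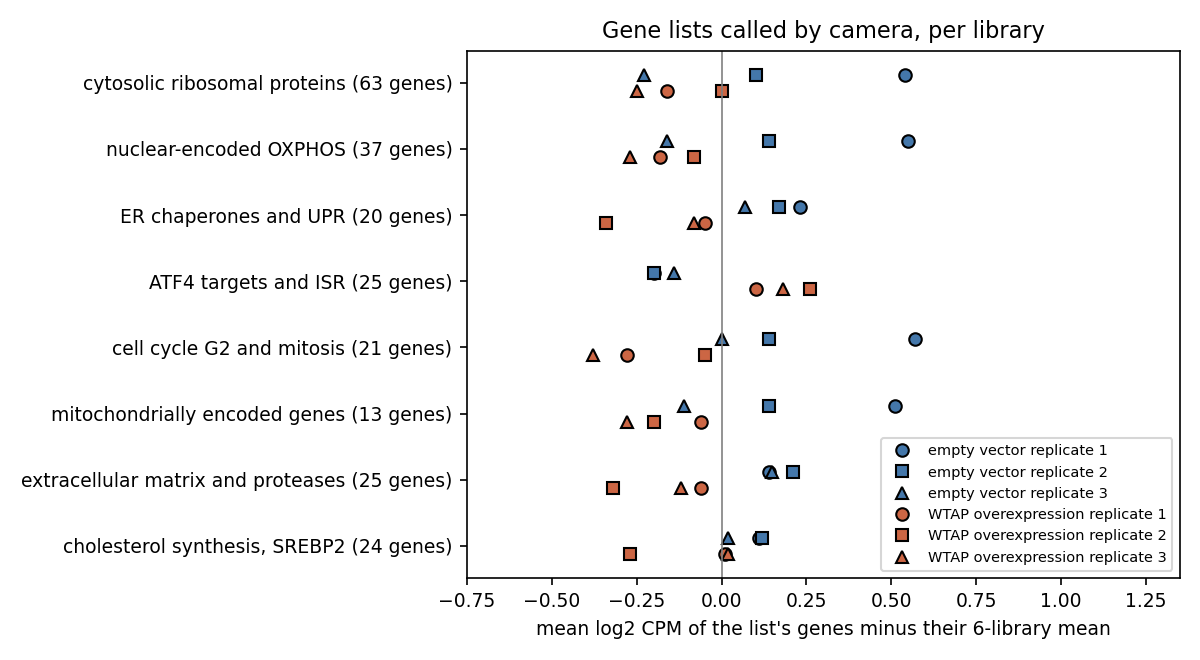
Mean log2 CPM of the members of each of the 8 lists called by camera, minus their mean over the 6 libraries; colours mark the groups and symbols the replicates. The ATF4, endoplasmic reticulum chaperone, matrix and G2 lists separate all libraries by group. For ribosomal proteins empty vector replicate 1 stands at 0.54 and empty vector replicate 3 at -0.23, among the WTAP-labelled libraries.

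Extracellular matrix and protease transcripts fell on balance. Of 25 members, 17 lay lower (13 of 24 on the TPM scale, with a median of -0.06 where the median gene lay at 0.12), 7 passed as lower and 1 as higher when adjusted over the list alone, and DESeq2 called 5, all lower (median -0.20, camera adjusted p = 0.00613; adjusted p = 0.637 with an estimated correlation). The collagenase MMP8 fell from 629.9 ± 127 to 305 ± 44.5 CPM (SD, n = 3 each; -1.05 ± 0.17 SE), the metalloprotease inhibitor TIMP1 from 624 ± 118 to 315 ± 45.9 CPM (-0.99 ± 0.17), and MMP1 by 1.17 ± 0.29. TGFBI, a secreted adhesion protein, lay higher at 632 ± 508 against 228 ± 51.5 CPM (1.47 ± 0.46). DESeq2 did not call it, and its log2 fold change was 0.56 without WTAP-labelled replicate 2. Without empty vector replicate 3 the list's adjusted p was 0.0559 and its median -0.14.

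Ribosomal protein, respiratory chain and mitochondrial transcripts lay lower, and all 3 lists stood highest in empty vector replicate 1. All 63 ribosomal protein genes lay lower (49 on the TPM scale), with a median of -0.29 (camera adjusted p = 1.25e-06; adjusted p = 0.726 with an estimated correlation), but none passed over the list alone. Empty vector replicate 1 stood 0.54 above the 6-library mean of this list, and without it the adjusted p was 0.122 and the median -0.08. Without empty vector replicate 3 the median was -0.48. Shorter genes as a whole lay lower: the shortest 10% had a median log2 fold change of -0.20, and they stood 0.31 above their 6-library level in empty vector replicate 1. RPS28 (-0.55 ± 0.22 SE) and RPL38 (-0.57 ± 0.24) had the smallest p, and lay at -0.27 and -0.23 without that library. Of 37 nuclear-encoded oxidative phosphorylation genes, 34 lay lower, with a median of -0.38 (camera adjusted p = 1.25e-06; adjusted p = 0.676 with an estimated correlation). DESeq2 called ATP5MC1, a subunit of ATP synthase, and COX5B, a subunit of cytochrome c oxidase, which went from 131 ± 54.0 to 72.6 ± 3.22 CPM. Without empty vector replicate 1 the list's adjusted p was 0.00222 and its median -0.18, ATP5MC1 lay at -0.49 and COX5B at -0.50. All 13 mitochondrially encoded genes lay lower (11 on the TPM scale; median -0.28, camera adjusted p = 0.000549; adjusted p = 0.676 with an estimated correlation), led by MT-CO3 (-0.56 ± 0.17) and MT-ND3 (-0.89 ± 0.29, or -0.56 without empty vector replicate 1). The mitochondrial list had 0.0379 without empty vector replicate 1 (median -0.14) and 0.11 without the 2 libraries farthest apart (median -0.10). Without empty vector replicate 3 the median of this list was -0.42. Once each library's trend on gene length was removed, it had 0.0744, oxidative phosphorylation 0.000686 and ribosomal proteins 0.0381. MT-CO3 shares positions with MT-ATP6. Empty vector replicate 1 also had the highest mitochondrial share of counts, 1.91%, against 1.21% to 1.49% in the other 5 libraries.

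Transcripts of the G2 and mitotic phases fell, though most were scarce. Of 21 members, 19 lay lower (median -0.50, and -0.12 for the 8 abundant enough to test on the TPM scale; camera adjusted p = 1.5e-05; adjusted p = 0.676 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 31.2 ± 1.84 to 15 ± 5.26 CPM (SD, n = 3 each; -1.06 ± 0.22 SE), and NDC80 lay at 0.499 ± 0.0592 against 1.25 ± 0.359 CPM. This list, too, stood highest in empty vector replicate 1, at 0.57 above its mean; without that library its median was -0.22 and its adjusted p 0.0105, and without WTAP-labelled replicate 3 its median was -0.33. S phase genes did not pass (camera adjusted p = 0.0577). This p was 0.00962 without WTAP-labelled replicate 2, 0.0432 without empty vector replicate 3 and 0.0387 with the gene length trend removed. Of 22 members, 17 lay lower, among them CDC45 (-1.11 ± 0.42) and TYMS (-1.12 ± 0.40, or -0.55 without empty vector replicate 1), which overlaps ENOSF1. On the TPM scale 10 of 19 lay lower, with a median of -0.03 where the median gene lay at 0.12. Cholesterol synthesis genes lay slightly lower, with 21 of 24 lower and a median of -0.19, against 16 of 24 and -0.07 on the TPM scale (camera adjusted p = 0.0157; adjusted p = 0.676 with an estimated correlation). No member passed over the list alone; EBP had -0.47 ± 0.15 and DHCR7, the enzyme of the last step, lay higher at 1.06 ± 0.35, and at 0.65 without WTAP-labelled replicate 2. The adjusted p was 0.239 without WTAP-labelled replicate 2 (median -0.11), 0.06 without empty vector replicate 2 (median -0.22) and 0.291 without the 2 libraries farthest apart (median -0.05).

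The M2 markers, the state the cells were driven to, were mixed and leaned lower. Of 22 measured, 13 lay lower and 9 higher, with a median of -0.31 and a camera adjusted p of 0.0691. This p was 0.0235 without empty vector replicate 1, 0.00752 without WTAP-labelled replicate 2, 0.0206 without WTAP-labelled replicate 3 and 0.0164 on log2(TPM + 1). With the stricter filter it was 0.0346, and without the 2 libraries farthest apart 0.00148. TGM2, a transglutaminase induced by interleukin-4, fell from 4273 ± 532 to 2237 ± 640.0 CPM (SD, n = 3 each; -0.93 ± 0.20 SE, DESeq2 adjusted p = 0.00141). The lectin CD209 fell from 302 ± 5.25 to 190.4 ± 50.7 CPM (-0.66 ± 0.18, DESeq2 adjusted p = 0.0353). MRC1, which encodes the mannose receptor, lay at -0.28 ± 0.27, CCL22 at -0.77 ± 0.24, and the scavenger receptor CD163 at 1.06 ± 0.40, the last 2 at -0.51 and 0.31 without WTAP-labelled replicate 2; none of these 3 was called. M1 markers went both ways (11 of 24 higher, median -0.05, mean 0.05, camera adjusted p = 0.848): TNFSF10 (1.11 ± 0.25) was called higher, IL1B (-0.92 ± 0.26) was called lower, and the co-stimulatory CD86 (0.62 ± 0.17) passed only over the list alone.

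**Figure D4:**
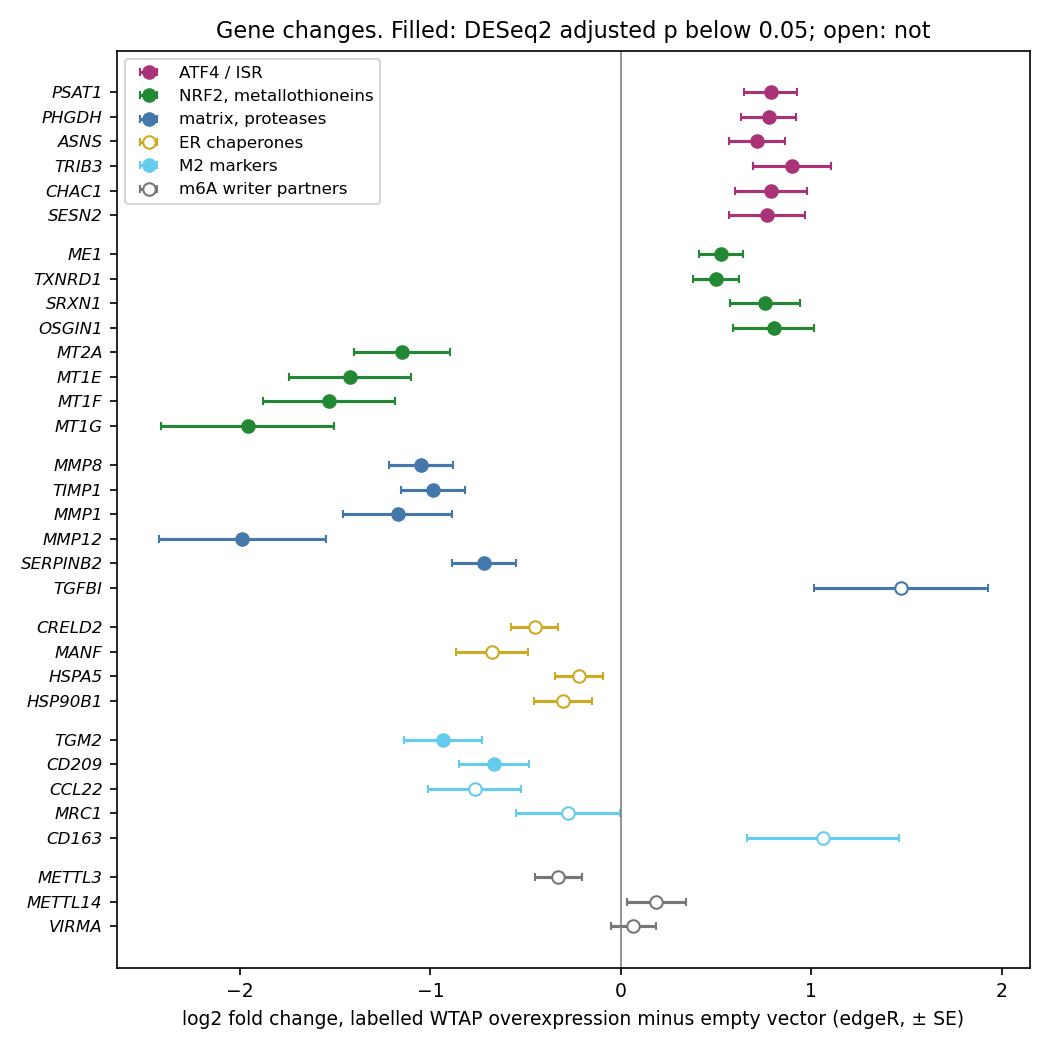
Log2 fold change of selected members of 6 lists, labelled WTAP overexpression minus empty vector, from edgeR with its SE; filled points have a DESeq2 adjusted p below 0.05. The ATF4 targets shown and ME1, TXNRD1, SRXN1 and OSGIN1 lie to the right of 0, and the metallothioneins and the matrix genes shown except TGFBI lie to the left.

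Antioxidant genes and metallothioneins, fixed as a single list, moved apart, and the list was not called (camera adjusted p = 0.287; median 0.12, mean -0.12). As higher, 6 of 20 members passed when adjusted over the list alone, and as lower, 5. ME1, the NADPH-making malic enzyme, rose by 0.53 ± 0.11 SE, TXNRD1 by 0.50 ± 0.12, SRXN1 by 0.76 ± 0.18 (0.49 without WTAP-labelled replicate 2) and OSGIN1 by 0.80 ± 0.21, all called. The metal-binding MT2A fell from 19.5 ± 7.13 to 8.82 ± 1.15 CPM (SD, n = 3 each), and MT1E, MT1F and MT1G were called lower too; these copies resemble each other closely, so the split of reads between them is uncertain. Inflammasome genes also went both ways (camera adjusted p = 0.615): NLRC4 was called higher (0.72 ± 0.16), and NLRP3 (-0.47 ± 0.11) and IL1B lower. In the NF-kB list (0.832; median 0.01, mean -0.13), CXCL8 rose by 0.50 ± 0.13 and was called, while CCL20 lay at -1.28 ± 0.33 and was not. In the list of lipid handling by LXR and PPARG (0.593), 15 of 21 members lay lower, though PDK4 (0.92 ± 0.21) and the lipid droplet protein PLIN2 (0.56 ± 0.15) were called higher.

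No other list passed camera. Camera adjusted p was 0.139 for type I interferon-stimulated genes (24 of 36 lower, but 17 of 36 on the TPM scale; PARP9 -0.38, which overlaps DTX3L; SAMD9L -0.28), 0.162 for glycolysis (PKM -0.28; TPI1 -0.24), 0.173 for heat shock (HSPB1 -0.42; SERPINH1 -0.25) and 0.188 for hypoxia targets (MXI1 0.66; ADM 0.66). The interferon list lay below its 6-library mean in WTAP-labelled replicates 1 and 3 (-0.28 and -0.23) and above it in replicate 2 (0.39). Its adjusted p was 2.17e-08, lower, without WTAP-labelled replicate 2, and 0.985, higher, without WTAP-labelled replicate 1. On the TPM scale the majority of members also turned to higher for glycolysis (14 of 22, against 8), MHC class I (8 of 15, against 2), lipid handling (14 of 21, against 6), MHC class II (4 of 6, against 3 of 7), M1 markers (12 of 20, against 11 of 24), T and NK cells (3 of 3, against 1) and B cells (2 of 3, against 1). The median gene itself lay at 0.12 on that scale, against -0.005 with TMM. Of the lists just named, MHC class II alone had a median above that (0.131). The rest had medians from 0.031 to 0.098, so these counts do not show a turn against other genes. Glycolysis had 0.0105 without empty vector replicate 1 and hypoxia targets 0.0285 without WTAP-labelled replicate 2. It was 0.256 for TGF-beta targets (TGFBI 1.47; SMAD7 0.34), 0.259 for MHC class I (TAP1 -0.22; ERAP2 0.30), which had 0.00752 without WTAP-labelled replicate 2, and 0.865 for MHC class II (RFX5 -0.17; CD74 0.17; median -0.11, mean 0.007). It was 0.617 for p53 targets, where PHLDA3 (-0.85 ± 0.20 SE) was called lower and TNFRSF10B (0.53 ± 0.14), which overlaps RHOBTB2, was not. It was 0.865 for immediate early genes (FOSB 0.69; KLF6 0.45) and 0.884 both for splicing regulators (SRSF1 -0.25; HNRNPA1 -0.23) and for lysosome and phagocytosis genes, where the Fc receptor FCGR2B (-0.57 ± 0.13) was called lower and FCGR2A (-0.39 ± 0.11) was not. Without WTAP-labelled replicate 2, ADM lay at 0.43, KLF6 at 0.25 and TGFBI at 0.56, and SMAD7 lay at 0.20 without empty vector replicate 1.

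Markers of cell states and of other cell types gave no called list. Camera adjusted p was 0.334 for PMA-differentiated macrophages (APOE -0.56; SPP1 -0.40), 0.615 for undifferentiated THP-1 cells and promyelocytes (RNASE2 -0.75; CD14 0.51, which turned to -0.35 without WTAP-labelled replicate 2), and 0.0629 for dendritic cells, where CD1C (-0.84 ± 0.17 SE) and CD1E (-1.25 ± 0.29) were called lower. The dendritic list had 0.0465 without WTAP-labelled replicate 1 and 0.00583 on log2(TPM + 1). Of markers of cells not used here, B cells (0.207) had 3 tested members, among them FCRLA (-1.23) and PAX5 (0.33, but -0.24 with limma-voom). PAX5 ran from 0.089 to 0.624 without 1 library. Fibroblasts (0.207) had 3, among them PDGFRA (-1.45 ± 0.32, called) and PDGFRB (-0.70). Endothelial cells (0.34; ESAM -0.61; ROBO4 -0.51) and T and NK cells (0.673; GNLY 0.36; NKG7 -0.17; median -0.07, mean 0.04) had 5 and 3. Without WTAP-labelled replicate 2, T and NK cells had 0.0292 and GNLY lay at -0.75, and NKG7 lay at 0.10 on the TPM scale. Epithelial and erythroid markers had too few expressed members to test (0 and 1). As signs of RNA quality, replication-dependent histones had 0.287, and 0.00576 without WTAP-labelled replicate 2 (H2BC21 -0.34; H2AC18 -0.54) and nuclear long non-coding RNAs 0.673 (NEAT1 0.70 ± 0.19, called higher; SNHG5 -0.48). Without WTAP-labelled replicate 2, PDGFRB lay at -0.42, ESAM at -0.36, ROBO4 at -0.77 and H2AC18 at -0.83. Without empty vector replicate 1, H2AC18 lay at -0.34 and SNHG5 at -0.16. ESAM lay at -0.95 without WTAP-labelled replicate 1, ROBO4 at -0.30 without WTAP-labelled replicate 3 and SNHG5 at -0.73 without empty vector replicate 3.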

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

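Fits without the 2 libraries farthest apart, DESeq2 without single libraries and the gene length and GC corrections were chosen after the data were seen. The number of called genes depended on the test and the libraries. Besides the 0 of edgeR (1813 at an unadjusted p under 0.05), DESeq2 called 198 genes (66 higher, 132 lower, 78 at least 2-fold), limma-voom 2296 (1094, 1202, 324) and edgeR with no filter on low counts 659 (234, 425, 188). Limma-trend called 2 (all higher, 2 at least 2-fold) on log2(TPM + 1) and 1 (higher, at least 2-fold) on log2(TPM + 0.1). Median-of-ratios factors, library size alone, the stricter filter and TPM above 0 in any library gave 0. Leaving out 1 library gave 0 to 62 genes (0 to 12 higher, 0 to 50 lower, 0 to 44 at least 2-fold), with 62 without empty vector replicate 3. Leaving out the 2 libraries farthest apart gave 508 (182, 326, 54), of which 138 were DESeq2 calls of all 6 libraries, and 358 with DESeq2. DESeq2 called 24 to 626 genes without 1 library. All 198 DESeq2 calls kept their direction in each fit of the table of settings that held them. At least 189 of them had groups that did not overlap, so their direction could hardly turn, and this does not test the calls. The cause of the differing counts was not tested.

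The replicate block gave 35 genes (2 higher, 33 lower, 26 at least 2-fold) and 9 lists, with S phase genes added at an adjusted p of 0.0297; it changed no other call of a list. Deviations of same-numbered libraries had correlations of 0.026, 0.017 and 0.026, so the numbers did not pair the samples. The log2 fold change of WTAP stayed above 0 in every setting, from 0.06 to 0.22 without 1 library and 0.14 with the replicate block. It was not called in any setting by p adjusted over all genes. Unadjusted, p was 0.0456 by edgeR without empty vector replicate 1. With limma-trend it was 0.0441 on log2(TPM + 1), 0.0448 on log2(TPM + 0.1) and 0.0178 for TPM above 0 in any library.

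Camera called 8 lists, 0 with an estimated correlation and 7 to 14 without 1 library, with 14 without WTAP-labelled replicate 2. Fry called 2, the ATF4 targets and the writer partners of WTAP. The directions of the 8 lists held in all planned settings. Of 554 list results in other settings, 478 kept their direction and side of the threshold, 22 lost and 24 gained a call, and 30 turned in direction. Of 2364 such results for 141 genes, 1977 kept both, 373 gained a call and 14 turned. CD14 turned to -0.101 with limma-voom, -0.115 without the 2 libraries farthest apart and from -0.35 to 0.808 without 1 library. GNLY turned to -0.545, -0.625 and from -0.747 to 0.731 in the same settings, and PAX5 to -0.237 with limma-voom. On the TPM scales NKG7 turned to 0.098, 0.116 and 0.098, and METTL14 to -0.011, -0.022 and -0.011. RBM15B turned to -0.034 without the 2 libraries farthest apart. Lists turned at these adjusted p without those 2 libraries: M1 markers at 0.52, immediate early genes at 0.566, heat shock at 0.566, lysosome at 0.165 and undifferentiated THP-1 markers at 0.792. With the length trend removed, NF-kB turned at 0.986, MHC class II at 0.885, T and NK markers at 0.84 and histones at 0.986. Immediate early genes turned at 0.962 on TPM, lysosome at 0.991 with fry and MHC class II at 0.988 with the stricter filter. Without 1 library, adjusted p ran from 0.508 to 0.954 for M1 markers, 2.17e-08 to 0.985 for interferon genes, 0.39 to 0.928 for NF-kB, 0.409 to 0.954 for immediate early genes and 0.0755 to 0.946 for heat shock. It ran from 0.409 to 0.86 for splicing regulators, 0.544 to 0.823 for lysosome, 0.374 to 0.993 for MHC class II, 0.144 to 0.835 for undifferentiated THP-1 markers, 0.0292 to 0.982 for T and NK markers and 0.00576 to 0.954 for histones. The cause was not tested.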

Other observations

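The genes, the MMP and metallothionein sets, the KEGG pathways, the gene length and GC corrections, the WTAP limit, ratio and WTAPP1 tests, and the edgeR splits were chosen after the data were seen. Fits that left out 1 library were planned, but the reading of those without empty vector replicate 1 as a test of 1 library was chosen after its result was seen. Among other genes that DESeq2 called, the myeloid transcription factor IRF8 fell from 37.0 ± 5.99 to 18.8 ± 3.42 CPM (SD, n = 3 each; log2 fold change -0.98 ± 0.17 SE, DESeq2 adjusted p = 0.000321). The calcium-binding protein S100A6 fell from 298 ± 128 to 130.4 ± 21 CPM, F3, which encodes tissue factor, by 0.99 on the log2 scale, and the growth factors HBEGF and AREG by 0.71 and 0.81. MARCKS rose from 15.2 ± 0.982 to 30.7 ± 8.51 CPM (1.01 ± 0.19). The ATP-gated channels P2RX7 (1.08) and P2RX4 (0.77) and the adenosine receptor ADORA2B (1.04) were called higher, as were the glutathione reductase GSR (0.59), TRIM16 (0.82) and the haem transporter SLC48A1 (0.69). Without WTAP-labelled replicate 2, P2RX4 lay at 0.43 and SLC48A1 at 0.42.

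All 6 tested matrix metalloprotease (MMP) genes of the cluster on chromosome 11 lay lower under each of the 4 scalings, with a mean log2 fold change of -1.08: MMP8 (-1.05), MMP12 (-1.99), MMP1 (-1.17), MMP10 (-1.47), MMP7 (-0.40) and MMP3 (-0.40, which ranged from -0.61 to -0.23 without 1 WTAP-labelled library). DESeq2 called MMP8, MMP12 and MMP1 but not MMP10 (adjusted p = 0.154), MMP7 (0.247) or MMP3 (0.514), and called 0 of the other 7 MMP genes, which had a mean of 0.221, with 3 lower, and 0 lower on the TPM scale. WTAPP1, a pseudogene of WTAP, lies inside this cluster on GRCh38 (chromosome 11, 102746968 to 102836766) and had a count of 0 in all 6 libraries. The difference between the 2 sets of MMP genes was not tested. Metallothioneins, which bind zinc and copper, lay lower for 5 of 5 tested genes (mean -1.368; MT1X at -0.77, or -0.49 without empty vector replicate 1, was not called), while 13 of the 15 other members of that list lay higher (median 0.244; 15 of 15 on the TPM scale). The zinc importers SLC39A14 (-0.57 ± 0.14 SE) and SLC39A10 (-0.72 ± 0.18) were called lower by DESeq2.

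Of 329 KEGG pathways of 10 to 300 tested genes, camera called 18, all lower. Of these, 10 were also called both without empty vector replicate 1 and with the gene length trend removed. Among the 10 were the Parkinson, Huntington, prion and Alzheimer disease pathways. KEGG pathways can share genes, so the 10 need not be separate results, and their overlap was not counted. With an estimated correlation 0 of the 18 were called (adjusted p = 0.982 for each). Oxidative phosphorylation had a median log2 fold change of -0.293 over 117 genes (camera adjusted p = 6.9e-09, and 0.00307 without empty vector replicate 1), and ECM-receptor interaction had -0.223 over 46 genes (0.0419, and 0.00257 without that library). Ribosome went from 7.28e-08 to 0.225 without that library.

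WTAP was not higher by the test in the libraries labelled WTAP overexpression. Too few reads is argued against by the upper 95% limit of the fold change, 1.319. A swap between libraries is argued against by the ratio of the highest to the lowest library, 1.291, since no library stood high. WTAPP1 held 0% as many counts as WTAP, which argues against reads given to the pseudogene. The lower 95% limit for SOD2 was -0.1787 (log2), which argues against a large fall of the antisense gene. If counting did not use strand, SOD2 reads may be part of the WTAP counts. SOD2 had 5.11 times the counts of WTAP, so a fall within its interval could then still hide a rise. The limit for WTAP and the ratio above would then bound the mixed counts and not WTAP alone. A low share of transfected cells, loss of the plasmid transcript before harvest and an insert whose reads were not counted may each have played a part, and none was tested.

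ATF4 targets lay higher, and this list was called in 6 of the 6 fits that left out 1 library, which argues against a single library carrying it. It was also called by camera after removal of each library's trend on gene length (adjusted p = 9.39e-06). This moved members' fold changes by up to 0.268 (log2), and those of all genes by up to 0.569. The list's median went from 0.371 to 0.365, so that trend accounts for little of the difference. Removal of the GC trend moved no gene by more than 0.0337, so the call after it decides nothing, but a trend of that size is far below the list's mean difference of 0.361 ± 0.052 (log2, SE over libraries). With an estimated correlation the adjusted p was 0.457 (0.0123 unadjusted), and the estimate was 0.026. That setting leaves camera only the residual degrees of freedom of 6 libraries. The lost call therefore does not show that correlated members made it. Fry, which does not compare a list with other genes, called this list (adjusted p = 0.0328). A stress response to the WTAP plasmid, or a difference in culture between the groups, may underlie the higher ATF4 list, and the design cannot tell these apart.

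Ribosomal protein, respiratory chain and mitochondrial transcripts lay lower, and all 3 lists stood highest in empty vector replicate 1. Without that library the adjusted p was 0.122 for ribosomal proteins, in line with 1 library carrying the call, 0.0379 for mitochondrially encoded genes (median from -0.279 to -0.141; 0.11 without the 2 libraries farthest apart), which leaves it open, and 0.00222 for oxidative phosphorylation (median from -0.376 to -0.181), which argues against it as the whole cause but not as a part of it. With the gene length trend removed the camera adjusted p was 0.0744 for mitochondrially encoded genes, as a length bias predicts. It was 0.0381 for ribosomal proteins (median from -0.289 to -0.085), which leaves a length bias open. For oxidative phosphorylation it was 0.000686 (median from -0.376 to -0.161). The preset correlation limits that p too, so it does not decide whether a length bias was the whole cause. Both lost calls came with a smaller median log2 fold change, from -0.289 (SD over members 0.158) to -0.082 (0.089) for ribosomal proteins without that library, and from -0.279 (0.265) to -0.125 (0.121) for mitochondrially encoded genes with the trend removed. An effect of the WTAP plasmid on these transcripts stays open and was not tested.

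The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes with edgeR, as did all 10 splits (highest other 0), and 1813 genes at an unadjusted p under 0.05 (highest other 1062; 1 split as large, the real one). It gave 198 genes with DESeq2 (highest other 20; 1 split as large, the real one) and 8 lists (highest other 11; 4 splits as large, the real one included).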
